A study of Oryzias latipes with 10 samples.

How the data were processed

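Liver RNA of medaka under long days, sampled at noon, was analysed in 5 libraries of wild-type (WT) and 5 of phod1 knockout (KO) fish. Groups and replicate numbers came from the sample labels, which name the libraries WT1 to WT5 and KO1 to KO5 and give neither sex, age nor batch. Per the labels, libraries were made with Lasy-Seq, a multiplexed 3' RNA-seq method. The submitters' processing notes name BWA 0.7.17-r1188 and Salmon 1.4.0, with no role for either; the genome build was not given in the sources used here. The authors deposited 1 table of RPM values (reads per 1000000 reads) for 25795 genes. Each library's values sum to 1000000, with no division by gene length. All 25795 gene IDs were matched by ID to a RefSeq gene table (assembly ASM223467v1), used only for names and for which genes lie next to each other. No gene of that table is named phod1 or pd1, also among synonyms, so the test planned for the targeted gene could not be run.

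The values kept the sequencing depth, since 100.0% of them were whole multiples of the smallest value above 0 in their library, within 1e-06 of a read (largest distance 1.1e-09). The inverse of that value gave totals of 5785650, 5713134, 5422342, 6619777 and 9803543 reads for WT1 to WT5. The totals of KO1 to KO5 were 6004500, 4542721, 8133600, 8371495 and 10112313 reads. A single read was worth 0.0989 to 0.220 RPM. In KO5 this step lies close to 0.1, so its values were also checked for rounding, and 0 of them were multiples of 0.1. KO5 was nevertheless left out of the count tests, as a precaution, and these covered 9 libraries. Pairs of libraries of the same group were compared by a chi-square over genes, and the ratio to its degrees of freedom was 14.6 to 140.1, so no library was counted as a duplicate.

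Genes with at least 1 RPM in at least 5 of the 10 libraries were tested, which left 14984 genes, 8058 with a symbol and 6926 known by a LOC number. Fold changes are KO minus WT on the scale of log2(RPM + 1), which understates the change of genes with low values. limma 3.58.1 in R 4.3.3 was used with a variance trend (limma-trend), no covariates, two-sided tests and Benjamini-Hochberg adjustment, with a threshold of 0.05. RPM were used as deposited, without further scaling. Values in the text are means ± SD over 5 libraries of RPM, and fold changes ± SE of the limma fit. With 5 against 5 libraries, chance gives no overlap between groups in 0.794% of genes.

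Gene lists for liver pathways and for cell types that the tissue could hold, 37 in all with 13 marker lists, were matched by symbol, with fish paralog suffixes allowed. The 30 lists with at least 5 tested members were compared with all other tested genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry were alternatives. Groups, the limma and camera tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the 12 largest rises and the 12 largest falls with a symbol and an adjusted p under 0.05. It adds up to 4 members of each list that passed camera or held at least 2 called members, taken by smallest p, and up to 3 members by highest mean RPM of the clock, egg protein, growth and marker lists. This gave 104 genes, of which 42 passed limma, and other genes are said to have been named after their values were seen. The result of 1 gene that the rule names is not reported here.

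The limma and camera steps were tested on simulated data of the same size, with 200 of 14984 genes changed. For KO against WT they called 62% of 4-fold and 9% of 2-fold changes, and 4.05% of the calls were unchanged genes. With no gene changed there were 0 gene calls and 0 list calls. In the real data, however, a split of WT1, WT4, WT5, KO1 and KO2 from the rest called 0 genes but 13 lists. The simulated 0 therefore does not measure false list calls in the real libraries. Raised 4-fold, genes had a median estimate of 1.84 log2 units, and raised 2-fold of 0.96.

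Alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 5 RPM, TMM, median-of-ratios and quantile scaling, robust variance estimates, library weights, the replicate number as a block, an adjusted p under 0.1, a size of at least 1 log2 unit and leaving out each library in turn. Reads recovered from the RPM of 9 libraries were tested with the quasi-likelihood test of edgeR 4.0.16, which called 131 genes higher and 47 lower, and with DESeq2 1.42.0, which called 310 and 179. Both are alternatives to limma on the deposited RPM. Leaving out WT3 with KO2, leaving out WT5 with KO1, rescaling without the 20 most abundant genes and matching lists by exact names were added after the data were seen. The tests were repeated on 100 of the 126 ways to part the 10 libraries into groups of 5, drawn with seed 1. Figures and remaining tests used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Coordinates and sequence were not used here, since the build of the deposited table is not stated, and genes that share reads with near-identical copies were not separated.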

Results

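Liver RNA of medaka (Oryzias latipes), a small freshwater fish, was compared between wild-type animals (WT) and animals whose phod1 gene, also written pd1 in the labels, had been knocked out (KO). All fish were held under long days and their livers were taken at noon. Each genotype had 5 libraries, made with Lasy-Seq, a method that sequences the 3' ends of transcripts. The libraries held 5422342 to 9803543 reads in WT and 4542721 to 10112313 in KO. Values were in RPM, reads per 1000000 reads, and 1 read was worth 0.0989 to 0.220 RPM. The question was which liver transcripts differ when phod1 is lost. No entry of the gene name table carried the name phod1 or pd1, so the knockout could not be checked at its own transcript. The labels name neither sex nor age nor batch, and nothing says how the animals were drawn, so p-values measure only the spread between these samples.

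Knockout liver held less messenger RNA for egg proteins and for many genes of protein folding in the endoplasmic reticulum (ER). Single genes of glucose and fat metabolism, such as gck, g6pc and thrsp, and the plasma protein genes hpx and serpinf2 were higher. Among genes with a symbol, the largest falls included vit-6 and ol-vit1, vitellogenin genes that encode yolk precursors secreted by the liver. They also included 1-sf (synonym l-sf), a choriogenin gene of the egg envelope. The largest rise of a gene with a symbol was that of plcb1, a phospholipase C of G protein signalling, from 4.32 ± 1.88 to 60.2 ± 30.7 RPM (mean ± SD, n = 5 per group), a log2 fold change of 3.42 ± 0.36 (SE) with no overlap between the groups. In the limma test, 175 of 14984 genes were higher and 252 lower in KO at an adjusted p under 0.05. Of these, 142 and 207 differed by at least 1 log2 unit. Among these 427 genes, 234 had no overlap between the groups, and 543 of all tested genes had none, against 118.9 (0.794%) that chance gives. The median log2 fold change of all genes was -0.19, and -0.01 after scaling by TMM. With TMM the split became 313 higher and 132 lower, with median-of-ratios scaling 296 and 143, and with quantile scaling 231 and 165. Without WT3 the counts were 365 and 479, while the edgeR count test on 9 libraries called 131 and 47. Of these, 163 were shared with limma, and 20 of the 42 named genes that passed limma did not pass edgeR.

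**Figure D1:**
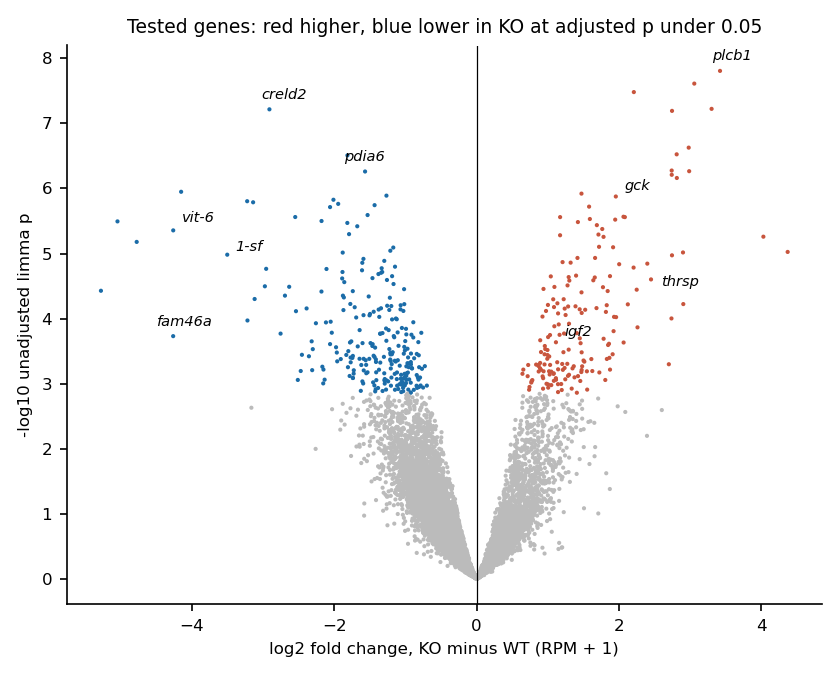
Each point is 1 of 14984 tested genes, with its log2 fold change (KO minus WT, on RPM + 1) across and the negative log10 of its unadjusted limma p upward. Red points are the 175 genes higher and blue points the 252 genes lower in KO at an adjusted p under 0.05; plcb1 lies at 3.42 and vit-6 at -4.26.

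Egg protein transcripts were 4.60 to 8.67 times higher in WT by the ratio of group means, and 16 to 41.3 times without KO2. Leaving out any other single library gave 3.85 to 10.4 times. The RPM of vit-6 was 17338 ± 7807 in WT and 2000 ± 3535 in KO, with a log2 fold change of -4.26 ± 0.67 and a limma adjusted p of 0.00165. For 1-sf it was 47034 ± 22877 against 7035 ± 10871 RPM (-3.51 ± 0.59, limma adjusted p = 0.00289), and for ol-vit1 41443 ± 16862 against 9004 ± 14372 RPM (-3.12 ± 0.60, limma adjusted p = 0.00695). Without KO2 the log2 fold changes of vit-6, 1-sf and ol-vit1 were -5.13, -4.23 and -3.88. The estrogen receptor gene esr1, whose product drives vitellogenin transcription, fell from 102 ± 20.8 to 34.3 ± 33.6 RPM (-1.88 ± 0.36, limma adjusted p = 0.00646), with a KO mean of 19.4 RPM without KO2. WT3 had the lowest WT value and KO2 the highest KO value of each of these genes, and the groups overlapped in all of them. The value of esr1 was 69.2 RPM in WT3 and 94.2 in KO2. Together vit-6, ol-vit1 and 1-sf took 10.4%, 13.3%, 2.77%, 12.4% and 14.0% of the reads in WT1 to WT5, and 0.593%, 6.95%, 0.571%, 0.428% and 0.479% in KO1 to KO5. The fixed list of estrogen-responsive egg proteins matched esr1 alone under its symbols, so that list had no test. The genes 1-sf, vit-6 and ol-vit1 are named because their falls were among the 12 largest of genes with a symbol. With edgeR on the 9 libraries without KO5, the adjusted p was 0.135 for vit-6, 0.13 for 1-sf, 0.238 for ol-vit1 and 0.142 for esr1. With robust variance estimates limma gave 0.0678, 0.0796 and 0.118 for vit-6, 1-sf and ol-vit1.

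Genes of ER stress and the unfolded protein response fell together. Of 35 tested members, 24 fell, 1 rose and 10 did not pass in limma, and adjusted over the list alone 26 fell and 1 rose. The mean log2 fold change of the list was -1.0, with a camera adjusted p of 3.5e-19 (adjusted p = 0.301 with an estimated correlation). creld2, an ER protein induced by unfolded proteins, fell from 286 ± 111 to 37.4 ± 19.9 RPM (-2.91 ± 0.34, limma adjusted p = 0.00016), with all 5 KO libraries below all 5 WT libraries, as in hsp90b1 and pdia6. The chaperone gene hsp90b1 fell from 1493 ± 456 to 392 ± 148 RPM (-1.95 ± 0.29), and the protein disulfide isomerase genes pdia4 and pdia6 fell by 2.18 ± 0.33 and 1.57 ± 0.21 on the log2 scale. The 1 member that rose was ddit4, a stress-induced inhibitor of TOR signalling, from 28.1 ± 12.4 to 121 ± 51.7 RPM (2.06 ± 0.31). As for the egg proteins, WT3 had the lowest WT values of creld2 (105 RPM), pdia4 (377 RPM), hsp90b1 (701 RPM) and pdia6 (154 RPM). KO2 had the highest KO values of creld2 (70.2 RPM), pdia4 (442 RPM) and hsp90b1 (586 RPM), but not of pdia6. In pdia4 the KO2 value lay above that of WT3, so the groups overlapped. Another large fall was that of fam46a (-4.27 ± 0.92). Within the list, chac1, the gene of a glutathione-degrading enzyme induced in ER stress, fell too (-2.69 ± 0.51). Its call was lost in limma with robust variances (adjusted p = 0.114) and without a filter (0.0606). The serine synthesis gene phgdh and the asparagine synthesis gene asns, the latter also in the list, fell by 2.31 ± 0.56 and 2.16 ± 0.55 on the log2 scale (limma adjusted p = 0.0300 and 0.0389). Both calls were lost under TMM, at 0.0562 and 0.0650, and in 5 and 9 of the 10 fits that left out 1 library, at limma adjusted p-values up to 0.0900 and 0.131. The membrane repair gene myof (-2.63 ± 0.49), efcab1 (-2.51 ± 0.64) and fblim1 (-2.26 ± 0.47) completed the 12 largest falls of genes with a symbol. The level of fblim1 was low, at 7.76 ± 5.13 RPM in WT and 0.720 ± 0.857 in KO. The calls of efcab1 and fam46a were lost in 8 and 3 of the fits that left out 1 library, at limma adjusted p-values up to 0.123 and 0.0541. The call of fam46a was also lost with edgeR (adjusted p = 0.0922) and DESeq2 (0.0592), and in limma without a filter (0.0994) and with robust variances (0.167). Those of fblim1 and efcab1 were lost with edgeR, at adjusted p-values of 0.0951 and 0.0616. In limma, efcab1 was lost under TMM (adjusted p = 0.0637) and myof with robust variances (0.0678). The log2 fold change of fam46a was -5.40 without WT3 and -4.98 without KO2, that of asns -2.81 without WT3, and that of efcab1 -1.89 without WT5.

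**Figure D2:**
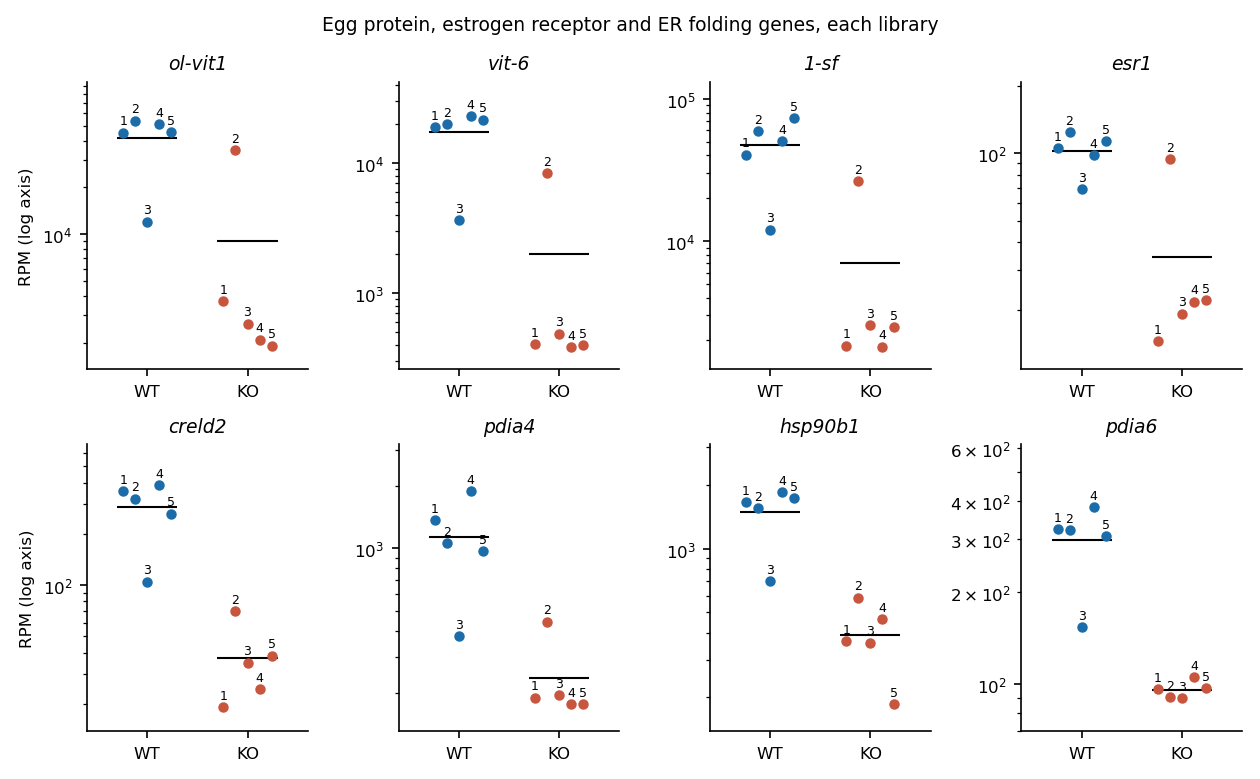
RPM on a log axis of 8 genes in each library, with replicate numbers above the points and a line at the group mean (5 WT in blue, 5 KO in red). In the egg protein genes and esr1, KO2 lies well above the other KO libraries, and WT3 has the lowest WT value in all 8 genes, as in pdia6 at 154 RPM.

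A few genes of glucose handling were higher in KO. In glycolysis and gluconeogenesis, 4 of 19 members rose and 15 did not pass, and 7 rose adjusted over the list alone (camera adjusted p = 1.0e-07; adjusted p = 0.301 with an estimated correlation). gck, the glucokinase that traps glucose in the hepatocyte, rose from 235 ± 118 to 842 ± 196 RPM (1.96 ± 0.28, limma adjusted p = 0.00111), and g6pc, the phosphatase that releases it, from 293 ± 141 to 1190 ± 434 RPM (2.08 ± 0.32, limma adjusted p = 0.00138). The glycogen phosphorylase gene pygl rose by 1.77 ± 0.28 and gapdh by 0.94 ± 0.23, and the call of gapdh was lost in 8 of the 10 fits that left out 1 library (limma adjusted p up to 0.0941). WT3 had the highest WT value of g6pc, at 478 RPM, and of pygl, at 294 RPM, but not of gck, at 131 RPM. In fatty acid and triglyceride synthesis 3 of 12 members rose, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.000567; adjusted p = 0.301 with an estimated correlation). These were thrsp, a regulator of lipogenesis (758 ± 367 to 4045 ± 1951 RPM, 2.45 ± 0.44), me1, a source of NADPH (1.73 ± 0.42), and the fatty acid synthase gene fasn (13.8 ± 11.4 to 45.6 ± 19.9 RPM, 1.91 ± 0.44). The calls of me1 and fasn were lost in 6 and 4 such fits, at limma adjusted p-values up to 0.105 and 0.0630, and with edgeR, at 0.0545 and 0.0822. Robust variances ended the calls of thrsp and fasn, at limma adjusted p-values of 0.0967 and 0.127. The elongase gene elovl5 stood at 84.9 ± 38.8 RPM in WT and 44.3 ± 21.5 in KO (limma adjusted p = 0.159).

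**Figure D3:**
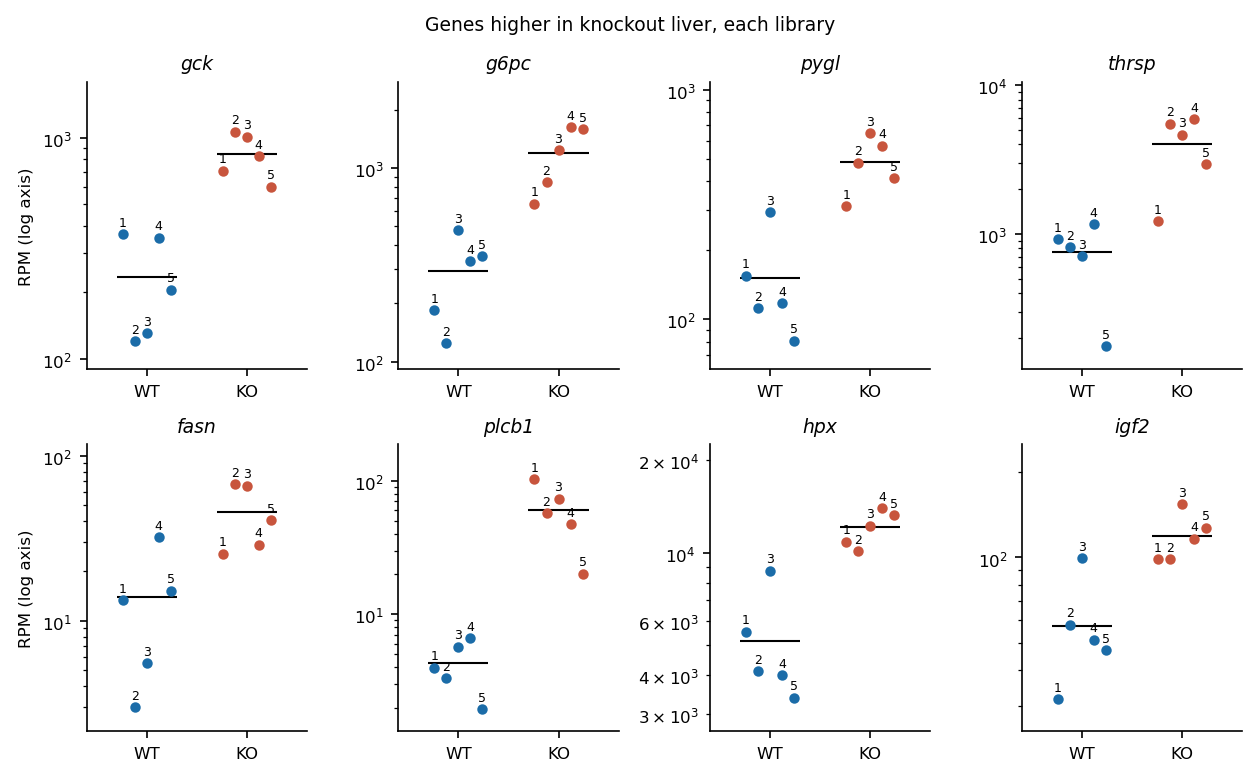
RPM on a log axis of 8 genes that were higher in KO, in each library, with replicate numbers and a line at the group mean (5 WT in blue, 5 KO in red). The groups do not overlap in gck, g6pc, pygl, thrsp, plcb1 and hpx, and they overlap in fasn and igf2.

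Among plasma proteins and other hepatocyte products, hpx and serpinf2 were higher in KO and most genes did not pass. Of 7 hepatocyte markers 1 rose, and 5 adjusted over the list alone (camera adjusted p = 7.7e-07; adjusted p = 0.301 with an estimated correlation). hpx, the heme-binding plasma protein hemopexin, rose from 5159 ± 2155 to 12080 ± 1598 RPM (1.30 ± 0.24, limma adjusted p = 0.00454), while rbp4 averaged 2853 ± 523 and 2910 ± 548 RPM. WT3 had the highest WT value of hpx, at 8746 RPM, and of serpinf2, at 399.6 RPM. Of 10 coagulation factors 1 rose, and 4 adjusted over the list alone (camera adjusted p = 6.0e-07; adjusted p = 0.301 with an estimated correlation). That gene was serpinf2, an inhibitor of plasmin (0.98 ± 0.19), and the fibrinogen genes fgb, fga and fgg had limma adjusted p-values of 0.0579, 0.0963 and 0.0664. The fibrinogen genes passed under TMM, at limma adjusted p-values of 0.0292, 0.0473 and 0.0294. Of 14 complement and acute-phase genes 1 rose, hpx again, and 1 adjusted over the list alone (camera adjusted p = 3.7e-07; adjusted p = 0.301 with an estimated correlation). Its members c9, c4b and lcn2 did not pass, at log2 fold changes of 0.65, 0.63 and 0.55.

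In amino acid catabolism and the urea cycle 3 of 39 members rose, and 5 adjusted over the list alone (camera adjusted p = 0.000254; adjusted p = 0.324 with an estimated correlation). They were ftcd of histidine breakdown (1.17 ± 0.18) and gstz1 and hgd of tyrosine breakdown (0.99 ± 0.23 and 0.77 ± 0.20). The member hal did not pass, at 0.61 ± 0.19, but did under TMM (limma adjusted p = 0.0189). In the growth and thyroid axis 2 of 15 rose, and 3 adjusted over the list alone (camera adjusted p = 0.00584; adjusted p = 0.324 with an estimated correlation). They were igf2, an insulin-like growth factor (57.5 ± 25.3 to 119 ± 23.3 RPM, 1.12 ± 0.25), and igfals, whose product carries such factors in blood (0.72 ± 0.18). The members dio1, foxo1 and ghr had limma adjusted p-values of 0.127, 0.35 and 0.777. In the oxidative stress response 1 of 21 rose, gclm of glutathione synthesis (1.01 ± 0.26), and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.00345; adjusted p = 0.301 with an estimated correlation). The members gpx1, taldo1 and prdx5 did not pass, at 0.85, 0.70 and 0.62, but did under TMM (limma adjusted p = 0.0308, 0.0301 and 0.0219). In steroid and glucocorticoid response 1 of 12 rose, the kinase gene sgk1 (1.48 ± 0.36), and 2 adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.324 with an estimated correlation). klf15, hsd17b3 and nr3c2 did not pass, at 1.22, -1.07 and -0.78, though klf15 did under TMM (limma adjusted p = 0.0324). The list's call was lost without WT5 and without KO5, at camera adjusted p-values of 0.0836 and 0.0806. None of 8 xenobiotic metabolism genes passed in limma, and 1 rose adjusted over the list alone (camera adjusted p = 0.00365; adjusted p = 0.301 with an estimated correlation). The fold changes of its members were cyp3a40 at 0.83 ± 0.23, cyp1a at 0.53 ± 0.29, mgst1 at 0.51 ± 0.19 and ephx1 at 0.35 ± 0.34. With TMM scaling cyp3a40 and mgst1 passed, at limma adjusted p-values of 0.0176 and 0.0498. Leaving out 1 library ended the calls of hgd and igfals in 8 of 10 fits, of gclm in 7, of sgk1 in 6, of gstz1 in 5 and of igf2 in 4, at limma adjusted p-values up to 0.107, 0.113, 0.130, 0.0815, 0.0801 and 0.0595. Other large rises were those of veph1 (2.40 ± 0.41), fam69c (2.26 ± 0.47), hsd17b14, a steroid dehydrogenase gene (2.25 ± 0.42), timp-2b (2.00 ± 0.35) and the transcription factor gene klf3 (1.92 ± 0.32). Levels were low for veph1 (0.434 RPM in WT, 6.61 in KO), fam69c (1.43 and 10.6) and timp-2b (0.461 and 4.82), so few reads carry their WT means. Without WT4 the WT mean of veph1 was 0.128 RPM. The call of hsd17b14 was lost with robust variances (limma adjusted p = 0.0950) and with edgeR (adjusted p = 0.0506). That of fam69c was lost in limma without a filter (adjusted p = 0.0721) and without WT5 and KO1 (0.0930).

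Cytosolic ribosomal protein genes lay close together below WT, with a mean log2 fold change of -0.28 and an SD of 0.08 over 66 members. None of them passed in limma, over all genes or adjusted over the list alone, and camera gave an adjusted p of 7.7e-07 (adjusted p = 0.570 with an estimated correlation). rps12 averaged 1982 ± 300 RPM in WT and 1401 ± 201 in KO, and rps18, rps21 and rps23 had log2 fold changes of -0.43, -0.46 and -0.47. Of 29 proteasome genes 1 fell, psmb4 (-0.84 ± 0.22), and 1 adjusted over the list alone (camera adjusted p = 0.0486; adjusted p = 0.563 with an estimated correlation), while psmd7, psmd6 and psma2 did not pass at -0.64, -0.60 and -0.52. Both list calls were lost under TMM, at adjusted p-values of 0.186 and 0.314, where the median of all genes was -0.01 and the list means -0.06 and -0.08. The proteasome call was also lost when WT2, WT4, WT5, KO1, KO2 or KO3 was left out alone, at camera adjusted p-values of 0.0950, 0.0547, 0.187, 0.0910, 0.298 and 0.0879, and with the replicate number as a block, at 0.0570. The call of psmb4 was lost under TMM, at a limma adjusted p of 0.164, and in 9 of the 10 fits that left out 1 library, at up to 0.138.

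**Figure D4:**
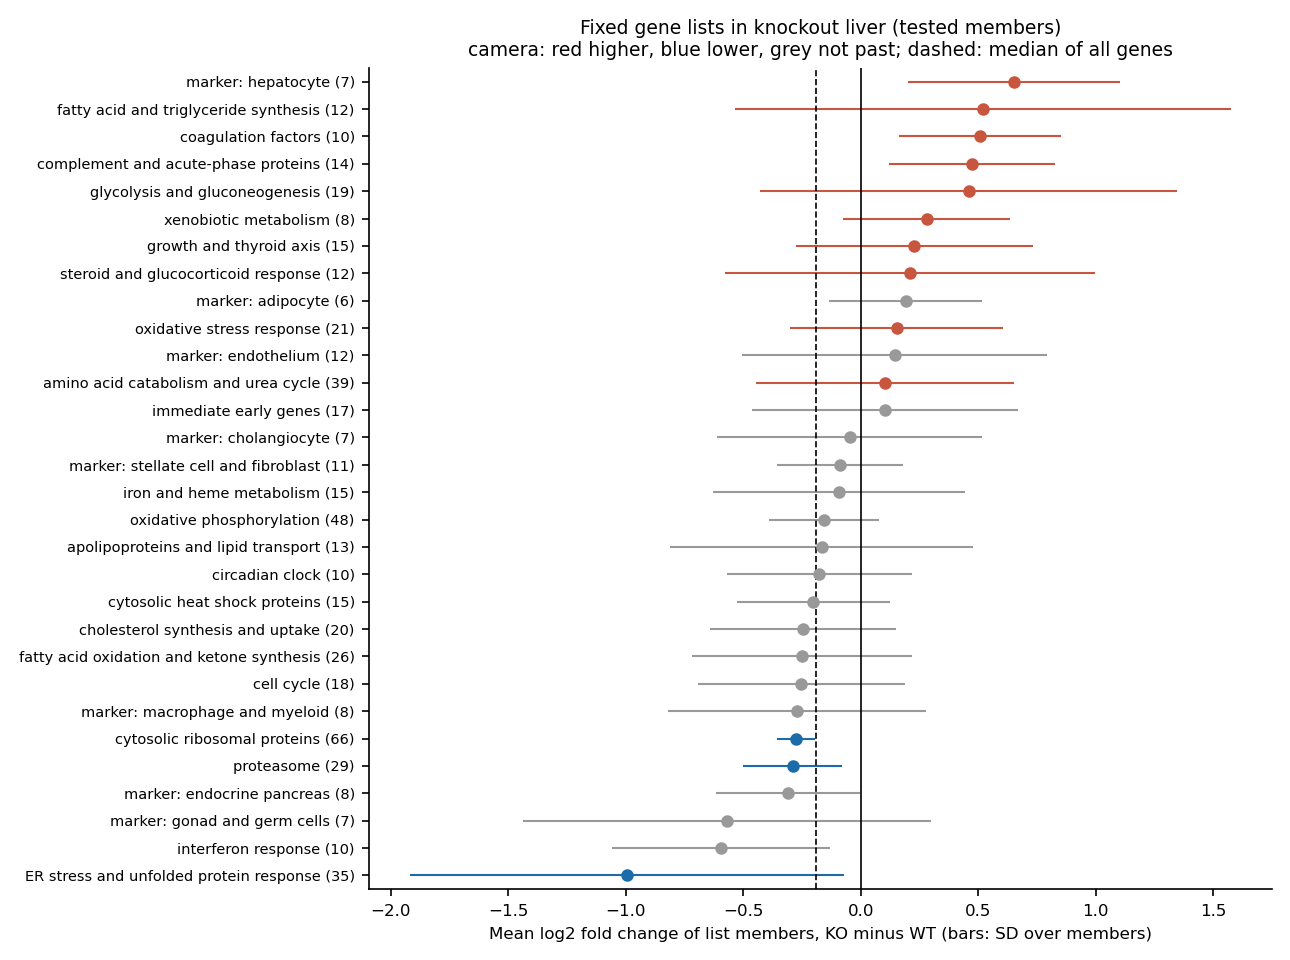
Mean log2 fold change (KO minus WT) of the members of each of 30 tested lists, with the SD over members as bars and the number of tested members in parentheses. Lists past the camera threshold are red when higher (10) and blue when lower (3), the rest are grey, and the dashed line marks the median of all genes at -0.19; ER stress and the unfolded protein response lies lowest at -1.0.

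The other lists did not pass camera. In the circadian clock none of 10 genes passed in limma and 1 fell adjusted over the list alone (camera adjusted p = 0.709), and hlf, csnk1e and csnk1d averaged 152, 28.4 and 25.4 RPM in WT against 132, 20.4 and 23.8 in KO. Of 26 fatty acid oxidation genes 1 fell over all genes and 1 adjusted over the list alone (camera adjusted p = 0.261). This was acaa2, a mitochondrial thiolase gene (-2.06, limma adjusted p = 0.00116), and among 13 apolipoprotein and lipid transport genes it was mttp (-0.77, limma adjusted p = 0.0295; camera 0.709), both named after their values were seen, and the call of mttp was lost in 8 of the 10 fits that left out 1 library, at limma adjusted p-values up to 0.0982. Of 15 iron and heme genes hpx rose by both counts (camera adjusted p = 0.584). No interferon response gene passed, and adjusted over the list alone 1 of 10 fell (camera adjusted p = 0.129), and no immediate early gene passed, with 2 of 17 higher adjusted over the list alone (0.108). Neither count held any gene in cholesterol synthesis and uptake (camera adjusted p = 0.940), oxidative phosphorylation (0.584), cytosolic heat shock proteins (0.726) or the cell cycle (0.734). Camera gave the direction up for iron and heme, apolipoproteins, cholesterol synthesis and the stellate cell, cholangiocyte and macrophage markers although their means were negative, and none of these lists passed. Immediate early genes had a mean of 0.10 and a median of -0.06.

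Markers of other cell types showed no common shift. Among gonad and germ cell markers, dnd1, a germ cell RNA-binding protein gene, fell from 20.5 ± 5.45 to 9.88 ± 0.727 RPM (limma adjusted p = 0.0359), a call lost under TMM (0.105), with edgeR (0.176) and in 9 of the 10 fits that left out 1 library (up to 0.131). Of 7 members 1 fell over all genes and 2 adjusted over the list alone (camera adjusted p = 0.261), and piwil2 and amh averaged 24.2 and 26.0 RPM in WT and 23.5 and 19.6 in KO. Of 12 endothelial markers the water channel gene aqp1 rose (66.8 ± 67.4 to 165 ± 68.3 RPM, limma adjusted p = 0.0306) over all genes and adjusted over the list alone (camera adjusted p = 0.0756), with a WT mean of 37.1 RPM without WT3, and its call was lost in 7 such fits (limma adjusted p up to 0.0972). The RPM of egfl7 was 24.1 in WT and 33.4 in KO, and that of ramp2 9.20 and 9.59. No member passed by either count in the markers of adipocytes (camera adjusted p = 0.192), endocrine pancreas (0.639), stellate cells and fibroblasts (0.639), cholangiocytes (0.709) and macrophages and myeloid cells (0.971). Their most abundant members averaged, in WT and KO, 260 and 299 RPM for g0s2, 41.0 and 29.9 for pcsk1, 24.4 and 24.4 for col6a1, 48057 and 41501 for anxa1, and 853 and 1171 for lyz. The source of the reads of anxa1, the cholangiocyte marker, was left undecided in the other observations. Its value may therefore not reflect cholangiocytes. Lists with under 5 tested members had no test. In them no member passed in limma apart from esr1. These lists were bile acid synthesis and transport and the markers of exocrine pancreas, erythrocytes, lymphocytes, intestine and muscle, besides egg proteins. The RPM of abundant markers among them in WT and KO was 73.0 and 34.2 for cpb1, 12.0 and 8.01 for epb41, 19.9 and 25.3 for cd4, 20.3 and 0.913 for fabp2, and 17.8 and 22.7 for tpm1. Without WT5 the WT mean of cpb1 was 39.2 RPM. The WT mean of fabp2 rests on WT5, at 97.0 RPM, where WT4 had 2.87 RPM and the highest KO library 1.67.

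A few abundant genes known only by number were chosen after their values were seen. LOC101159180 fell from 5179 to 392 RPM (-5.28, limma adjusted p = 0.00574) and LOC101171080 from 4902 to 450 RPM (-4.78, limma adjusted p = 0.00216). Both falls were larger than any called fall of a gene with a symbol. Neither gene passed edgeR (adjusted p = 0.198 and 0.139). LOC100049432 fell from 57370 to 7614 RPM (-3.23, limma adjusted p = 0.00116) and LOC100049191, the neighbour of 1-sf, from 22526 to 2058 RPM (-4.15, limma adjusted p = 0.00111; -4.86 without KO2). Without KO2 their KO means were 3998 and 666 RPM, and in both genes the KO2 value lay above that of WT3. LOC105357179 rose from 2556 to 19733 RPM (3.06, limma adjusted p = 0.00016), with the lowest KO library at 12201 RPM and the highest WT library at 3438 RPM. Also higher were LOC101169721 (26123 to 52643 RPM, limma adjusted p = 0.0239), LOC100144362 (21696 to 54734, 0.00884) and LOC101163028 (20912 to 44881, 0.00892). So were LOC101155461 (11942 to 27905, 0.00929) and LOC101173833 (5278 to 10929, 0.0122). LOC101169721 and the genes named after it all had their highest WT value in WT3. Of them, only LOC101163028 and LOC101173833 had no overlap between the groups.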

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

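All tests of explanations in this part were chosen after the results were seen. Outliers were sought in 88 groups of 5 values. These were the 42 named genes that passed limma, read depth and the share of egg protein reads, each in WT and in KO. A library was marked when its gap to the nearest other library exceeded 0.71 of the group's range, on log2(RPM + 1) for genes. In all 15 were marked, where chance marks about 1 in 20 groups, or 4.4 here. That number takes no account of genes that vary together. WT3 held 6 of the marks, KO2 6 and WT5 3.

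In WT3, fam46a stood at 1.66 RPM, against 107.9 to 156.3 in the other WT libraries, and myof at 11.6 against 41.0 to 65.4. The yolk precursor genes vit-6 and ol-vit1 stood at 3643 and 12020.1 RPM in WT3, against at least 18817 and 45018 in the other WT libraries, and the ER chaperone genes hsp90b1 and pdia6 at 701 and 154 RPM, against at least 1544 and 306. In KO2, vit-6 stood at 8323 RPM (384 to 490.1 in the other KO libraries), 1-sf at 26471 (1814 to 2571), ol-vit1 at 34684 (1914 to 3690.4), pdia4 at 442 (176 to 196) and esr1 at 94.2 (14.5 to 22.1). The egg protein genes took 6.95% of the reads of KO2, against 0.428% to 0.593% in the other KO libraries. In WT5, timp-2b stood at 1.12 RPM (0.184 to 0.35 in the other WT libraries) and thrsp at 175.5 RPM (708 to 1166), and its depth, in units of 1000000 reads, was 9.80 against 5.42 to 6.62.

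WT3 and KO2 lay between the other libraries in egg protein genes and in many other genes, so the calls were repeated without both, which gave 1045 genes. With exchanged labels, those genes should place WT3 near KO and KO2 near WT as often as other pairs fall with their own groups. For 16 other pairs, each left out when its own 1045 genes were chosen, this was 60.9% to 77.0%. The observed share was 22.4%, while 16.2% placed both libraries with the labels they carry and 47.8% placed both nearer KO. Neither labelling reached the share of the other pairs, so this test cannot decide on an exchange. A wrong label on WT3 alone cannot be told apart, because 70.2% of the genes placed WT3 nearer KO, below the 73.3% to 87.7% of other KO libraries and far above the 8.90% to 22.7% of other WT libraries. A state that goes with egg protein level and varies inside both groups may also account for much of the difference. Of the 1045 genes, 46.2% changed from WT3 to KO2 in the direction found without them, where 50.3% of all tested genes were lower in KO2. Among the ER stress genes called lower, 18 of 26 kept that direction although KO2 held more egg protein RNA. Their median change from WT3 to KO2 in that direction was 0.251 log2 units, against a median size of 1.37 without the pair. These are values of 1 pair of libraries, so they do not decide between that state and the knockout. The pair was chosen for its egg protein level and the labels give neither sex nor reproductive state, so what that state is was not tested, and an effect of the knockout stays open.

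Among 100 splits of the 10 libraries, 2 gave at least as many genes as the real 427, the real one included, so other groupings rarely reached this number. A chance imbalance of sex or reproductive state between the groups cannot be excluded, since the labels give neither. The highest other split, with 545 genes, exchanged WT3 with KO2, and the next highest gave 100 genes; a split above the real one points to a structure of the samples that the groups do not follow. For the lists, 8 of 100 splits gave at least 13, with 14 as the highest other, so chance cannot be excluded for the number of lists.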

How the results depend on the processing

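Of the counts with limma (175 genes higher, 252 lower) and camera (10 lists higher, 3 lower), those for pseudocounts, robust variances, rescaling without the 20 most abundant genes and exact list names stayed within 1.5 times. Without a filter 73 genes were higher and 103 lower, where more genes are tested. TMM gave 313 and 132 with 1 list lower, median of ratios 296 and 143 with 1, and quantile scaling 165 genes and 2 lists lower, and all 3 move the median of all genes up, by 0.185, 0.171 and 0.194 log2. Library weights gave 322 and 435 with 2 lists lower, a filter of 5 RPM 2 lists lower, and an adjusted p under 0.1 273 and 443. On 9 libraries, edgeR gave 47 genes lower and 1 list lower, and DESeq2 310 genes higher and 1 list lower. An estimated correlation left 0 lists higher and 0 lower, fry 0 higher and 1 lower, ER stress (fry adjusted p = 0.0388). Added after the data were seen, leaving out WT3 with KO2 gave 424 and 621 with 2 lists lower, and WT5 with KO1 102 and 93 with 2. The cause was not tested for these, apart from fewer libraries.

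Leaving out 1 library gave 94 to 365 genes higher, 104 to 479 lower, 9 to 12 lists higher and 2 to 4 lower. Counts moved by over 1.5 times without WT1 (103 higher, 104 lower), WT2 (106, 127), WT3 (365, 479), WT4 (98, 109), WT5 (109, 137), KO4 (94, 139) and KO5 (95, 143), and the lower count also without KO1 (167) and KO3 (166). Cholesterol synthesis and uptake, not called with all libraries, reversed without KO3 to a call below other genes (mean -0.70, camera adjusted p = 0.00215), and its mean ranged up to 0.034 without WT5. Camera also called endothelial markers without WT3 (adjusted p = 0.0199), KO3 (0.0466) or KO4 (0.0425), immediate early genes without KO3 (0.0429) and interferon response without WT1 (0.0313). Of 42 named genes that passed, 20 were lost with edgeR, 21 without a filter, 15 with robust variances, 5 with TMM and up to 15 without 1 library; 0 reversed.

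With the replicate number as a block, 145 genes were higher, 190 lower and 2 lists lower, with 313 of the limma calls shared. Deviations of same-numbered libraries correlated at -0.081, 0.001, -0.011, -0.042 and -0.011, and no library matched its own number best. These values gave no sign of pairing by number, but they cannot show how the animals were kept or handled. In KO2, the shallowest library, 1 read is worth 0.220 RPM, so genes near 1 RPM rest on few reads.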

Other observations

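The tests of an abundant neighbour, of a chromosome segment and of a common source were stated before their results were seen, while that of curated entries and all genes named in this part were chosen afterwards.

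Genes called in KO lay next to each other in the genome more often than shuffled gene orders gave. Of the called genes, 33 neighbouring pairs changed in the same direction, against a mean of 6.21 and a highest value of 16 in 2000 shuffles. Pairs included 1-sf with LOC100049191, g6pc with LOC101169348, pdia4 with pkd1l1, gstz1 with aldh6a1, and the run from ol-vit1 to vit-6. Reads that run on from neighbours of at least 5000 RPM were argued against as the whole cause. With genes within 10 places of such a gene set aside, 23 pairs were left, against a mean of 5.38 and a highest value of 15. Run-on from less abundant neighbours, as from pdia4 at a mean of 683 RPM to pkd1l1 at 23.2 RPM, was not tested. A single chromosome segment carried along with the knockout was argued against as the source of most pairs, which were spread over 17 chromosomes. The chromosome that held most had 5, where random placement reached 6 at its 95th percentile. A segment that adds only some pairs cannot be excluded by this test, and the place of phod1 was not known here. Related gene copies that lie together were not tested and stay a possible explanation.

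The genes six3, foxa3, ptbp2, cyp11b and anxa1 averaged 15016, 2680.1, 5326, 7237 and 44779 RPM and varied little, with coefficients of variation of 0.0627, 0.0523, 0.0648, 0.0649 and 0.117, against a median of 0.176 over 154 abundant genes. Together they took 6.47% to 8.49% of the reads of each library. A common source of these reads could not be decided, since the median SD of the log2 ratios between pairs was 0.0883, between the 0.05 that a common source would need and the 0.1 that would exclude it. The gene set of this test was corrected after a first result, which had excluded a common source, because it held a near-silent entry of the same name as ptbp2. Reference entries made of curated transcripts alone, which all 5 genes have, cannot be told apart either, because among other abundant genes such entries made up 2 of 12 among the least variable and 13 of 137 in the rest (Fisher's exact test, two-sided p = 0.346), too few to decide.

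With the egg protein level as a covariate limma called 0 genes, with 1143 at an unadjusted p under 0.05. This level, the mean of vit-6, ol-vit1 and 1-sf, which were called themselves, had a correlation of -0.817 with the group, so this fit does not separate it from the genotype. Over the 427 genes called without it, the median size of the log2 fold change went from 1.34 to 0.76 and the median SE from 0.28 to 0.45, and 416 had the same sign. The fold change of plcb1 was 3.36 ± 0.64 with the covariate, and its limma adjusted p went from 0.00016 to 0.232.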
